A study of Mus musculus with 12 samples.

How the data were processed

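The series holds 12 one-colour Affymetrix arrays of mouse muscle, 3 for each of KO soleus, WT soleus, KO TA and WT TA. Per the labels, total RNA was extracted with Trizol, converted to biotin-labelled cRNA and hybridised, and the submitters' processing notes name MAS5 without a version or a role. The deposited table gives log2 signal for 45101 probe sets per array, from 0.89 to 16.36, with 0 missing values and a floor near which much of the table lies. Its low end lacks the wide scatter of log2 MAS5 signals, and the summary method is not given in the sources used here, so the values were used as log2 signals as given and no pseudocount was added in the main setting. Groups and replicate numbers were taken from the sample titles, and 0 columns were left unmapped. The labels do not say whether soleus and TA of equal number came from one mouse, nor how the 3 replicates were obtained beyond calling them biological.

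The 2% trimmed means of the unlogged arrays differed by up to 1.11 times, above the limit of 1.1 set before the data were examined, so the arrays were quantile normalized. Probe sets above the 40th percentile of their array (log2 2.76) on at least 3 of the 12 arrays were kept, which left 27497. This percentile lay in the floor of the table, so a filter on a mean log2 above 5 was added as an alternative after the data were seen. Gene symbols came from a probe table, which gave 1 symbol to 34945 probe sets, several to 932 and none to 9160, and 64 were controls. Probe sets without a single symbol were left out of the gene tests. For each gene the probe set with the highest mean was tested, giving 13009 genes, of which 5643 had other kept probe sets. Of the 13009, 12950 matched a RefSeq gene table of another source. It was used for gene order, transcript type and current symbols, which changed the symbol of 0 tested genes. Its synonyms were also used to match members of the gene lists.

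Genes were tested in R 4.3.3 with limma 3.58.1, by lmFit on 4 group means over all 12 arrays and eBayes with a variance trend. Tests were 2-sided, with Benjamini-Hochberg adjustment over all genes of a comparison and a threshold of 0.05. The comparisons were KO against WT in soleus and in TA, the difference of these effects, soleus against TA in WT and in KO, and the genes called in both muscles. With 3 arrays against 3, an exact permutation test of a single gene cannot go below p = 0.1, so the linear model that shares the spread over genes was used. Log2 differences are given with the standard error of the model. The median standard error was 0.18 for a comparison of groups and 0.25 for the difference of effects.

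A total of 32 gene lists, 23 of pathways and 9 of cell type markers, were fixed before the data were examined and tested with camera on the same model, with a preset correlation of 0.01 and adjustment over the lists within each comparison. Camera asks whether a list moved relative to all other genes. Beside it stand camera with an estimated correlation and fry, which asks whether a list's genes moved, on balance, one way. The list test was first run without the variance trend; that run is given as the alternative without a trend. For the robust and animal block alternatives, camera was run on the moderated statistics. Lists needed at least 5 measured genes, and counts of list members are given over all genes and adjusted over the list alone.

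The genes named in the text follow a rule fixed before the data were examined. H6pd is always given. For KO against WT the rule takes the 12 highest and 12 lowest log2 differences among genes past the test whose KO and WT values do not overlap, and where fewer than 5 genes pass also the 10 of smallest p. For the difference of effects it takes the 6 highest and 6 lowest, for WT soleus against TA the 8 highest and 8 lowest, and for every list up to 4 members past the test or, with none past, up to 2 given as values. Members are given for the lists the text describes.

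Whether equal replicate numbers pair the arrays was judged by the correlation of deviations from the group means. Between KO and WT TA it was 0.35, 0.16 and 0.56 for numbers 1, 2 and 3; between the KO muscles 0.49, 0.43 and 0.59; between the WT muscles 0.35, 0.14 and 0.59. These exceed the limit of 0.1, although unequal numbers reached 0.24, 0.10 and 0.35 in the same comparisons. KO and WT soleus (0.43, 0.09 and 0.61) and WT soleus and KO TA (0.28, 0.04 and 0.44) fell short of it at number 2. Results with the replicate number as a block are therefore given beside the TA and the muscle comparisons where they differ. The source of this pairing is these values and not the labels. KO soleus and WT TA (0.28, 0.26 and 0.47) exceeded the limit too, though arrays of different genotype cannot share a mouse. Deviations of the 3 arrays of a group cancel out. Where number 3 stands apart in each group, numbers 1 and 2 thus tend to deviate alike across groups. The limit therefore does not show that equal numbers share a mouse.

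Alternatives were a pseudocount of 1 or of the median on the unlogged values, no filter and a stricter one (mean above the 50th percentile), the table as deposited, median centring, all kept probe sets, no trend, robust and array weights, only the arrays compared, replicate block and animal block, a 1.5-fold minimum, the other probe sets of a gene, and leaving out each array. Leaving out all arrays numbered 3, the filter on mean log2 above 5, the block with fry or with an estimated correlation, and the blocks for the mean of both KO effects were added after the data were seen. The code was tested on simulated data with the series' own spread and 200 changed genes. For KO against WT TA, 60.4% of genes changed 2-fold and 91.2% of those changed 4-fold were recovered, with 5.3% false calls; for soleus these were 64%, 91% and 5.5%, and for the difference of effects 39.4%, 76.4% and 5.2%. A list shifted by 0.5 on the log2 scale was found in 10 of 10 simulations of each comparison. The simulated genes varied independently and no simulated arrays stood apart as those numbered 3 do. These rates therefore test the code and need not hold for the real arrays, least of all for the lists. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Raw array images and cell files were not used here.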

Results

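Gene expression was measured in the soleus and the tibialis anterior (TA) of 4-week-old mice, either wild type (WT) or with a knockout (KO) of H6pd. H6pd encodes hexose-6-phosphate dehydrogenase, an enzyme of the endoplasmic reticulum (ER) lumen that makes NADPH there. Each of the 4 groups had 3 arrays, which the labels call biological replicates, and every array carried 45101 probe sets. Per the design text the mice had been weaned and their muscle showed no overt myopathy on histology. The muscles were chosen because their fibre types and metabolism differ. The small number of arrays per group limits the precision of every value. Eif2s3y, a Y-linked gene, lay between log2 10.31 and 10.99 on the 12 arrays and Xist, which marks female tissue, between 2.75 and 2.78, in the floor of the table.

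Muscle was the first source of variation. The first principal component held 46.6% of the variance, with soleus arrays between -42.4 and -19.9 and TA arrays between 25.3 and 43.2. On the component that followed, with 18.6% of the variance, the arrays numbered 3 of all 4 groups lay between -33.9 and -23.8, whereas the other 8 arrays lay between 5.8 and 21.9. The arrays numbered 3 were spread evenly over the groups, so that each comparison held as many of them on either side.

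**Figure D1:**
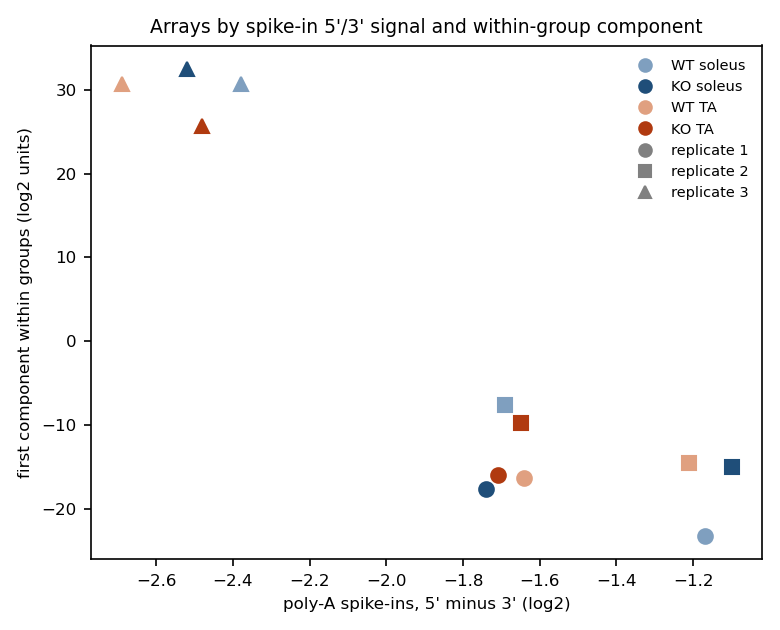
Position of the 12 arrays on the first component of variation within groups (y axis) against the difference of 5 prime and 3 prime signal of the poly-A spike-in controls (x axis, log2); colours are the 4 groups and shapes the replicate numbers. The arrays numbered 3 lie apart from the other 8 on both axes.

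The targeted gene itself was read by 1 probe set. In soleus, H6pd signal was 4.90 ± 1.04 (SD, n = 3, log2) on the arrays labelled KO and 6.27 ± 0.78 on WT arrays, a difference of -1.36 (SE 0.62, adjusted p = 0.577). In TA it was 6.96 ± 0.50 in KO and 6.85 ± 0.93 in WT, a difference of 0.11 (SE 0.62, adjusted p = 0.966). This sign turned when KO TA replicate 3 (-0.16), WT TA replicate 1 (-0.13) or WT TA replicate 2 (-0.19) was left out. Neither difference passed the test. The labels do not say which part of the gene was deleted or whether the probe set lies in it, so the genotype labels were used as given and were not checked by this signal.

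**Figure D2:**
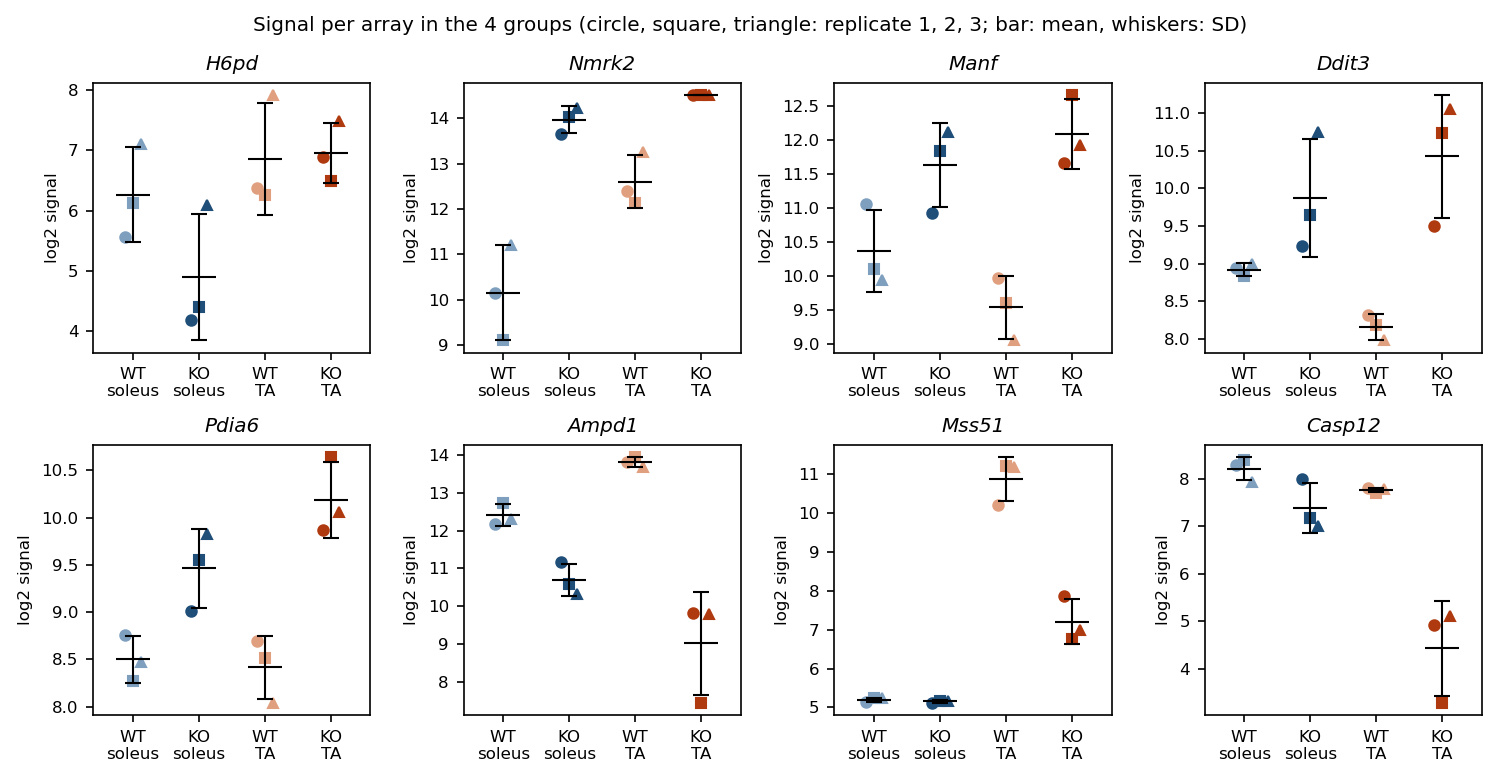
Log2 signal of 8 genes on each of the 12 arrays (y axis), by genotype and muscle (x axis), after quantile normalization; circles, squares and triangles are replicates 1, 2 and 3, the horizontal bar is the group mean and the whiskers are ± 1 SD. Ampd1, Mss51 and Casp12 were lower and Manf, Ddit3 and Pdia6 higher on all 3 KO TA arrays than on all 3 WT TA arrays, and Nmrk2 was higher on all 3 KO soleus arrays than on all 3 WT soleus arrays.

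KO TA had more of several ER folding transcripts than WT TA and far less of some other transcripts. Manf, a protein of the ER lumen induced by ER stress, was 5.8-fold higher in KO TA (log2 difference 2.54, SE 0.41, n = 3 arrays per group, adjusted p = 0.014). Ddit3, which encodes the stress transcription factor CHOP, was 4.82-fold higher (2.27, SE 0.42, adjusted p = 0.0235), although a dimmer probe set differed by 0.70 (adjusted p = 0.175). 2310065F04Rik, a long non-coding RNA also called linc-Myh, lies in the cluster of skeletal myosin heavy chain genes. It was at least 71.4-fold lower (-6.16, SE 0.18, adjusted p = 1.22e-07), a lower bound since its 3.26 ± 0.24 in KO is at background, against 9.42 ± 0.28 in WT. Ampd1, the AMP deaminase of skeletal muscle, was 27.8-fold lower (-4.80, SE 0.54, adjusted p = 0.00536).

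Among the other genes that rose in KO TA were Sdf2l1 (log2 difference 2.20) and Dnajb9 (1.96), co-chaperones of the ER chaperone Hspa5. Tmed3 (1.86), a cargo receptor between ER and Golgi, rose as well. Cnpy3 (2.14), an ER chaperone of Toll-like receptors, rose together with the receptor gene Tlr4 (2.09), although another probe set of Tlr4 differed by 0.22 (adjusted p = 0.718). Myom3 (2.36), a protein of the sarcomere's M-band, rose from 4.36 ± 0.12 to 6.72 ± 0.57 (mean ± SD, log2, n = 3), against 10.90 ± 0.10 in WT soleus. Cidea (2.44), a lipid droplet protein, Aldh18a1 (2.26), which starts proline synthesis, Gca (2.22) and Smtnl1 (2.02) completed the 12 highest. Cidea, Sdf2l1, Tlr4 and Cnpy3 lay near background in WT TA, at 3.64, 3.67, 3.63 and 3.93, so their differences are lower bounds. On other, dimmer probe sets, none past the test, Aldh18a1 differed by 0.07 to 1.11, Gca by 0.04 and Tmed3 by 0.09.

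Genes that fell in KO TA included Mettl21e (-3.77), a lysine methyltransferase, and Prima1 (-3.76), the membrane anchor of acetylcholinesterase. Mss51 fell by 3.66 on the log2 scale, from 10.86 ± 0.56 to 7.20 ± 0.58. Casp12 (-3.33), a caspase of the ER membrane, Slc30a2 (-3.32), a zinc transporter, the uncharacterised D930003E18Rik (-3.32) and BE949265 (-2.62), Atp13a5 (-2.90), a P-type ATPase, and Maob (-2.45), which encodes monoamine oxidase B, were also lower. Ighm, the immunoglobulin mu heavy chain, fell by 3.51 on the log2 scale on its brightest probe set. Its other probe sets were dim, at means of log2 2.88 to 3.68, and differed by -2.01 to 0.04, none past the test. For D930003E18Rik, BE949265 and Atp13a5 the KO TA means of 3.09, 2.25 and 2.70 were at background, so these falls are lower bounds. Those of Slc30a2 and Prima1, 4.05 and 4.27, were near it, so their falls may be larger than given. By the naming rule, the 3 KO and the 3 WT values of each of these genes do not overlap.

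In all, 368 of 13009 genes differed between KO and WT TA (limma), 185 higher and 183 lower in KO, and 160 of them by more than 2-fold. This balance depended on the scaling: the table as deposited gave 218 higher and 148 lower, and median centring 132 and 214. At an unadjusted p under 0.05 there were 2222 genes, where 650 would be expected by chance, and the groups did not overlap in 3020 genes, or 23.2%, against 10% by chance if all arrays vary alike. With the replicate number as a block 913 genes passed, including 367 of the 368. Fitted on the TA arrays alone 4 did, and without the arrays numbered 3 it was 56; leaving out KO TA replicate 2 gave 85 genes, KO TA replicate 3 gave 117, and WT TA replicates 1, 2 and 3 gave 178, 204 and 242.

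Of the 27 ER chaperones and folding enzymes, all had a higher mean in KO TA, 11 rose past the test over all genes and 21 when adjusted over the list alone. The median log2 difference of the list was 0.81. Beside Manf, Sdf2l1 and Dnajb9 it included Pdia6 (1.78, SE 0.27), a protein disulfide isomerase. The list was higher in KO TA than other genes (camera with a preset correlation, adjusted p = 4.36e-17, and adjusted p = 0.214 with an estimated correlation). By fry its adjusted p was 0.0055. Of 24 genes of ER-associated degradation and unfolded protein response signalling, 2 rose: Sec61b (0.90), a subunit of the ER translocon, and Derl1 (0.77), a component of the degradation channel. Adjusted over the list alone 8 rose (median 0.64, adjusted p = 1.53e-07, and adjusted p = 0.22 with an estimated correlation). Of 35 integrated stress response targets of ATF4 and CHOP, 3 rose: Ddit3, Aldh18a1 and the threonyl-tRNA synthetase gene Tars (0.53). Adjusted over the list alone 10 rose (median 0.41, adjusted p = 2.48e-06, and adjusted p = 0.535 with an estimated correlation). Fibroblast and matrix genes moved with these lists, at a median of 0.20 with 0 of 20 past the limma test, Postn differing by 0.62 and Fn1 by 0.47 (adjusted p = 0.0496, and adjusted p = 0.704 with an estimated correlation).

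Contractile and metabolic lists also shifted in KO TA. The 18 slow fibre genes had a median difference of 0.93, 17 of them higher, yet none passed over all genes and 4 rose adjusted over the list alone (adjusted p = 9.44e-06, and adjusted p = 0.372 with an estimated correlation). Myh7, the slow myosin heavy chain, differed by 1.89 (SE 1.09, adjusted p = 0.43) and Tnni1 by 1.65 (SE 0.49, adjusted p = 0.111). Much of this rested on WT TA replicate 3, without which Myh7 differed by 0.22, Tnni1 by 0.96 and the list by a median of 0.37, still called. Of 22 fast fibre genes 20 were lower, at a median of -0.19, with Ampd1 as the 1 that fell (adjusted p = 0.00472, and adjusted p = 0.535 with an estimated correlation). Fatty acid uptake and oxidation genes were higher (median 0.29, adjusted p = 0.00851, and adjusted p = 0.586 with an estimated correlation). Of these 32, Acaa2 (0.82) and Hadh (0.43), both enzymes of beta-oxidation, rose. Tricarboxylic acid cycle and respiratory chain genes were lower (median -0.12, adjusted p = 0.00304, and adjusted p = 0.535 with an estimated correlation), with 1 of 56, Cox5b (-0.36), past the test. Genes of calcium handling and excitation-contraction coupling had a median of -0.21 and 0 of 25 past the limma test, although Pln (1.30) and Sln (1.12), which are also slow fibre genes, had the largest differences (adjusted p = 0.026, and adjusted p = 0.535 with an estimated correlation). Without KO TA replicate 3 these were 0.81 and -0.11. Sln lay near background in WT TA, at 3.63, so the size of its difference cannot be read.

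Cytosolic ribosomal protein genes had a median of 0.25, with 21 of 24 higher and Rps4x (0.38) past the test (adjusted p = 1.53e-07, and adjusted p = 0.22 with an estimated correlation). Proteasome genes had a median of -0.23. Over all genes 0 of 31 passed limma, while 8 fell and 1 rose adjusted over the list alone, with Psmc3 and Psma7 both at -0.59 (adjusted p = 0.0016, and adjusted p = 0.372 with an estimated correlation). Cytosolic heat shock proteins had a median of 0.29, with Hspb1 at 0.98 and Hsph1 at -0.83, neither past the test (adjusted p = 0.02, and adjusted p = 0.535 with an estimated correlation). The 5 lymphocyte markers had a median of -0.10 and Ighm as the 1 that fell (adjusted p = 0.0248, and adjusted p = 0.393 with an estimated correlation). Leaving out single arrays ended the calls of the heat shock list (median 0.05 without WT TA replicate 3) and of the fatty acid oxidation (0.14 without WT TA replicate 1), calcium handling, lymphocyte and fibroblast lists. In total 13 of 32 lists were called, 0 with an estimated correlation and 6 by fry. With the replicate block fry called 9 and camera with an estimated correlation 0.

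Lists that camera did not call in KO TA in the main setting nonetheless held single genes that changed. Among 30 glucocorticoid-responsive genes (adjusted p = 0.26), Gadd45g (-2.11, SE 0.27) and Sgk1 (-1.04, SE 0.23) fell. Among 28 genes of glycolysis and glycogen metabolism (adjusted p = 0.986), the phosphorylase kinase subunits Phkg1 (-1.40) and Phka1 (-0.79) fell and the glycogen branching enzyme Gbe1 (1.08) rose. Sirt5 (0.93), a mitochondrial deacylase, rose in the NAD synthesis list (adjusted p = 0.911; the median was -0.03 and the mean 0.08). The antioxidant gene Mgst1 (-1.27), the immediate early gene Ier3 (-1.42), the tendon marker Thbs4 (-1.58) and the smooth muscle marker Lmod1 (-0.88) fell, in lists with adjusted p of 0.132, 0.288, 0.349 and 0.288. None passed in the lists of NADPH and pentose phosphate enzymes (0.552), muscle atrophy genes (0.859), fatty acid and triglyceride synthesis (0.0965), cholesterol synthesis (0.349), myogenic and denervation genes (0.288), clock genes (0.509), cell cycle genes (0.911), or markers of erythroid (0.0921), myeloid (0.89), endothelial (0.11) and Schwann cells (0.932). In the adipocyte list (0.0965) Cidea was the 1 that rose. With the replicate block camera also called the lists of fatty acid and triglyceride synthesis (higher) and erythroid markers (lower), 15 lists in all. With the block and an estimated correlation neither was called (adjusted p = 0.612 and 0.426). Fry called the erythroid list without the block (adjusted p = 0.0431) and with it (0.0294), and the antioxidant list with it (0.0335).

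**Figure D3:**
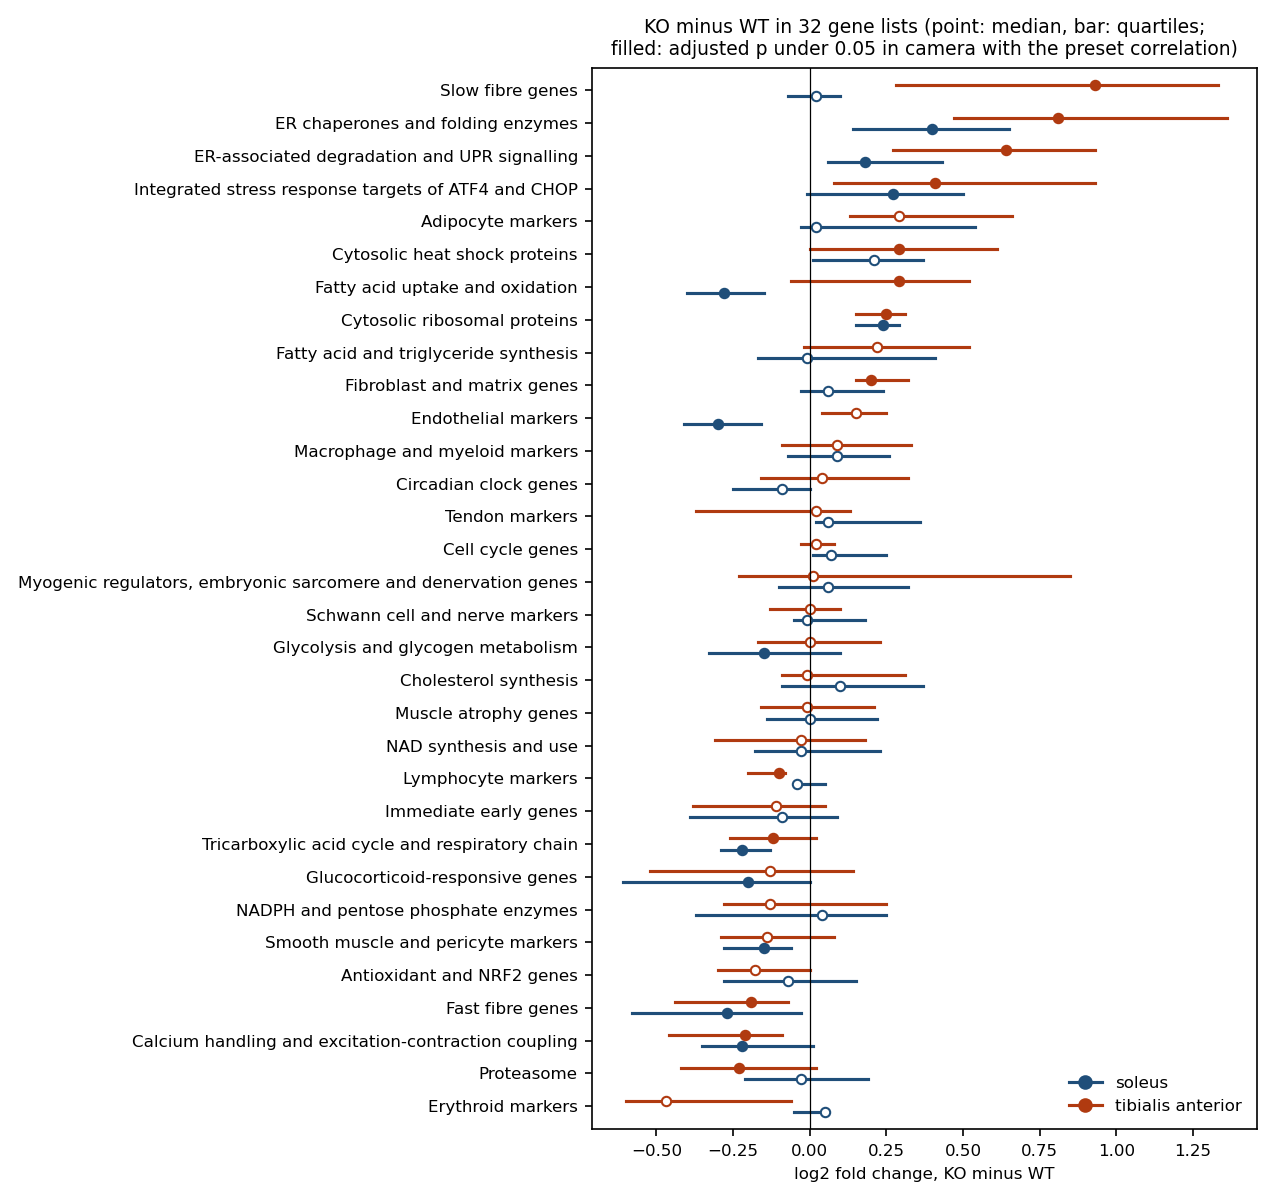
Log2 difference between KO and WT (x axis) in each of 32 gene lists (y axis) in soleus and TA; points are medians over the list's genes, bars run from the lower to the upper quartile, and filled points mark an adjusted p under 0.05 in camera with the preset correlation. ER chaperones lay at 0.40 in soleus and 0.81 in TA, and slow fibre genes at 0.02 and 0.93.

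In KO soleus, 4 genes passed the test. Nmrk2, a muscle kinase that feeds nicotinamide riboside into NAD synthesis, was 14.1-fold higher, at 13.97 ± 0.29 (SD, n = 3, log2) in KO against 10.15 ± 1.04 in WT (log2 difference 3.82, SE 0.45, adjusted p = 0.0351). Gprasp1, a sorting protein of G protein-coupled receptors, rose by 1.29 (SE 0.17, adjusted p = 0.0498). Dixdc1, a DIX domain protein of Wnt signalling, rose by at least 1.06 (SE 0.10, adjusted p = 0.00902), to a low signal of 4.55 ± 0.11 in KO. This is a lower bound, since the 3.49 ± 0.11 in WT was near background. Alas1, the first enzyme of haem synthesis, fell by 0.81 on the log2 scale (SE 0.10, adjusted p = 0.0351), but its other probe set, also bright, differed by -0.23 (adjusted p = 0.7). The 3 KO and 3 WT values of each of these genes did not overlap.

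Further genes with the smallest p did not pass: Fer1l6 (-2.15, adjusted p = 0.063), Apobr (1.03, 0.063), Clstn2 (-0.60, 0.063), Blnk (-0.73, 0.0824), Snhg6 (0.91, 0.0925) and Igsf1 (2.35, 0.104). At an unadjusted p under 0.05 there were 1140 genes, against 650 expected by chance, and 1556 genes (12%, against 10% by chance) did not overlap. The 10% holds for arrays that all vary alike, which those numbered 3 did not, so it is a rough mark here. Dixdc1 kept its call (adjusted p from 0.000383) under all alternatives run for it except the fit on the soleus arrays alone (0.333), in which limma called 0 genes. Nmrk2 kept a difference of 3.29 to 4.48 but, like Gprasp1 and Alas1, lost its call without KO soleus replicate 1 (0.0503), 2 (0.056) or 3 (0.0849), its adjusted p ranging from 0.00269 to 0.444 over its alternatives. The count was 10 without KO soleus replicate 2, 30 without WT soleus replicate 1, and 360 with array weights.

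The list of ER chaperones and folding enzymes was higher in KO soleus too, with 26 of 27 genes higher at a median of 0.40 (camera with a preset correlation, adjusted p = 3.47e-08, and adjusted p = 0.325 with an estimated correlation). None of its genes passed singly, in limma over all genes or adjusted over the list alone; Manf differed by 1.25 (SE 0.41, adjusted p = 0.359) and Dnajb9 by 1.18 (SE 0.40, adjusted p = 0.379). ER-associated degradation genes (median 0.18, adjusted p = 0.00383, and adjusted p = 0.457 with an estimated correlation) and integrated stress response targets (median 0.27, adjusted p = 0.00381, and adjusted p = 0.776 with an estimated correlation) were shifted upward, with 0 members past the limma test. Among the largest differences were Sec61b (0.65), Selenos (0.68), Mthfd2 (1.92) and Asns (1.15). Without KO soleus replicate 3 the ER chaperone median was 0.23, with 22 genes higher and still called, while Selenos differed by 0.42, Mthfd2 by 1.01, Asns by 0.35 and Dnajb9 by 0.76. Cytosolic ribosomal protein genes were higher in 23 of 24 cases (median 0.24), and 7 rose adjusted over the list alone, with Rpl14 at 1.79 and Rpl37 at 0.48 (adjusted p = 2.13e-12, and adjusted p = 0.178 with an estimated correlation). Endothelial markers (Flt1 -0.53, Eng -0.51, median -0.30, adjusted p = 0.00042, and adjusted p = 0.262 with an estimated correlation) and smooth muscle and pericyte markers (Smtn -0.47, Abcc9 -0.37, median -0.15, adjusted p = 0.0353, and adjusted p = 0.419 with an estimated correlation) were lower beside these lists. Without WT soleus replicate 3 Flt1 differed by -0.27, Smtn by -0.30 and Abcc9 by -0.21. Smtn differed by -0.78 without WT soleus replicate 1.

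Energy metabolism lists lay lower in KO soleus. Tricarboxylic acid cycle and respiratory chain genes were lower in 51 of 56 cases (median -0.22), 9 of them falling adjusted over the list alone (adjusted p = 1.04e-16, and adjusted p = 0.223 with an estimated correlation). Uqcrc1 (-0.50) and Cox7a1 (-0.45) had the largest differences, not past the test over all genes. Fatty acid uptake and oxidation genes had a median of -0.28, with 6 falling adjusted over the list alone (adjusted p = 5.72e-07, and adjusted p = 0.457 with an estimated correlation). Ppara, a transcription factor for these genes, differed by -2.14 and Acads by -0.72. Fast fibre genes had a median of -0.27 and 6 fell adjusted over the list alone, Ampd1 differing by -1.72 (adjusted p = 0.33 over all genes). The list's adjusted p was 1.23e-06, and adjusted p = 0.419 with an estimated correlation. Glycolysis and glycogen metabolism (Phkg1 -1.13, Phka1 -0.62, median -0.15, adjusted p = 0.00383, and adjusted p = 0.457 with an estimated correlation), calcium handling (Pln 2.15, Cacna1s -1.01, median -0.22, adjusted p = 0.0168, and adjusted p = 0.457 with an estimated correlation) and glucocorticoid-responsive genes (Arrdc2 -1.43, Gadd45g -0.99, median -0.20, adjusted p = 0.0268, and adjusted p = 0.776 with an estimated correlation) were shifted downward. Without KO soleus replicate 3 the lists of ER-associated degradation (median 0.00), stress response (0.02) and endothelial markers (-0.18) lost their calls, and without WT soleus replicate 3 the glucocorticoid list did (0.09). The smooth muscle and calcium handling calls also ended when single arrays were left out. The fast fibre median was -0.16 without KO soleus replicate 3 and -0.17 without WT soleus replicate 2, still called. That of the ribosomal list was 0.15 without WT soleus replicate 3, still called. The glycolysis median lay between -0.27 and -0.06 with single arrays left out. Without WT soleus replicate 3 Arrdc2 differed by 0.18 and Ppara by -1.34, and without KO soleus replicate 3 Pln by 1.34. In total 12 lists were called, 0 with an estimated correlation and 2 by fry, the ribosomal (adjusted p = 0.0205) and respiratory (adjusted p = 0.0391) lists. Slow fibre genes did not shift (median 0.02, adjusted p = 0.809), nor did the NAD list that holds Nmrk2 (median -0.03, mean 0.19, adjusted p = 0.852). Ankrd1, a stress-responsive ankyrin repeat protein, differed by 3.92 (SE 0.68, adjusted p = 0.113) and Myh3, the embryonic myosin heavy chain, by 2.94 (SE 0.56, adjusted p = 0.127), in a list of myogenic and denervation genes that did not shift (median 0.06, adjusted p = 0.339).

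Whether the muscles responded differently was tested as the KO effect in soleus minus that in TA. At an unadjusted p under 0.05 there were 743 genes, where 650 would be expected by chance. The effect differed for 5 genes past the test (limma). For 3 of them the fall was seen in TA: the difference was 5.55 for 2310065F04Rik (SE 0.25, adjusted p = 1.04e-05), 3.61 for Mss51 (SE 0.44, adjusted p = 0.0289) and 3.59 for Prima1 (SE 0.45, adjusted p = 0.0289), whose KO effects in soleus were -0.61, -0.05 and -0.17. Mss51 and Prima1 lost this call under 12 of 25 and 13 of 24 alternatives (adjusted p from 0.00556 to 0.385 and from 0.00335 to 0.253), among them 8 and 9 that left out a single array. Bhlha15 lost it under 7 of 23 (0.00011 to 0.0876), Arv1 under 4 of 24 (0.00221 to 0.105) and 2310065F04Rik under 0 of 24. In WT soleus 2310065F04Rik and Prima1 stood at 3.74 ± 0.24 and 3.89 ± 0.16, close to the floor of the array. The size of a fall there could not be read, so neither could the size of the difference between the muscles, and a fall as large in proportion as in TA is not excluded. Bhlha15, a secretory cell transcription factor (-1.50, SE 0.17, adjusted p = 0.0223), and Arv1, a lipid transport protein of the ER (-0.61, SE 0.06, adjusted p = 0.0116), had their highest group mean in KO TA, both near the floor, at 4.02 ± 0.33 and 3.61 ± 0.06.

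Fatty acid uptake and oxidation genes went apart between the muscles, being lower in soleus and higher in TA (median difference -0.51, 30 of 32 negative, Slc27a1 -1.22 and Acaa2 -1.01, adjusted p = 1.28e-11, and adjusted p = 0.338 with an estimated correlation). The ER chaperone list was raised less in soleus (Sdf2l1 -1.76, Manf -1.28, median -0.51, adjusted p = 2.21e-07, and adjusted p = 0.338 with an estimated correlation). The slow fibre list, higher in KO TA, did not shift in KO soleus (median 0.02). Its median difference of effects was -0.75 (Myh7 -2.01, Sln -1.71, adjusted p = 7.31e-05, and adjusted p = 0.433 with an estimated correlation). Sdf2l1 and Sln lay near background in WT TA, so the size of their differences cannot be read. In WT soleus Myh7 stood at 15.47, where the highest value of the table is 16.36, which leaves little room for a rise. All 14 endothelial markers had a lower KO effect in soleus (Pecam1 -0.79, median -0.47, adjusted p = 2.19e-05, and adjusted p = 0.335 with an estimated correlation). Proteasome genes had a positive difference (median 0.22, adjusted p = 0.00165, and adjusted p = 0.338 with an estimated correlation). Negative ones were seen for ER-associated degradation (-0.28, adjusted p = 0.00165, and adjusted p = 0.465 with an estimated correlation) and the stress response (-0.22, adjusted p = 0.00833, and adjusted p = 0.918 with an estimated correlation). The same held for glycolysis (-0.11, adjusted p = 0.0298, and adjusted p = 0.63 with an estimated correlation) and the respiratory chain (-0.06, adjusted p = 0.0029, and adjusted p = 0.776 with an estimated correlation). None of these lists held a gene past the limma test. Camera called 9 lists with the preset correlation, 0 with an estimated one, and fry called 0. Without WT TA replicate 3 the slow fibre difference was -0.26 and that of Myh7 -0.34, and the stress response, glycolysis and respiratory calls ended when single arrays were left out. The difference of Sln was -0.48 without KO TA replicate 3 and -2.75 without KO TA replicate 2. The count of 5 genes moved to 1 without a variance trend, and leaving out single arrays gave between 1, without WT soleus replicate 3, and 20, without KO TA replicate 1.

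The KO effects of both muscles went the same way in many genes. Across the 13009 genes they correlated at Pearson r = 0.51 and Spearman rho = 0.42, where genes are not independent replicates. Of the 368 genes called in TA, 327 (88.9%) had the same sign in soleus and 159 of these an unadjusted p under 0.05 there. The effects of the muscles may share error, since deviations of KO soleus and KO TA arrays of equal number correlated at 0.49, 0.43 and 0.59. The share of all genes with the same sign is not given here. No gene passed limma in both muscles (0, against 0.0427 higher and 0.0141 lower in both by chance). With the replicate block 2 did, Nmrk2 (3.82 in soleus and 1.92 in TA) and the lactate dehydrogenase gene Ldhd (-1.49 and -0.65), named after their values were seen. Nmrk2 stood at 14.52 ± 0.00 in KO TA after quantile normalization, which gives arrays equal values at equal ranks, and 12.60 ± 0.59 in WT TA (adjusted p = 0.0549 without the block and 0.0207 with it).

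WT soleus and WT TA were compared because the design rests on their fibre types. Soleus held far more of the slow contractile transcripts, among them Myh7, the slow myosin heavy chain (703-fold, log2 difference 9.46, SE 1.09, n = 3 arrays per group, adjusted p = 0.000681). Its WT TA values had an SD of 2.95, and without WT TA replicate 3 the difference was 7.79, or 221-fold. Sln, the calcium pump regulator sarcolipin, was higher too (8.67), as were the slow troponins Tnni1 (8.31), Tnnc1 (7.92) and Tnnt1 (7.58), the regulatory light chain Myl2 (7.06) and Tecrl (6.70). Tpm3, slow tropomyosin, was higher by 7.52 on its brightest probe set, and 2 others passed at 6.98 and 0.91, whereas 2 gave 0.80 and -0.08 and did not. Lower in soleus were the potassium channel Kcnc4 (-5.74), 2310065F04Rik (-5.67), Mss51 (-5.67), Ighm (-4.89), the uncharacterised BC023105 (-4.80), the tetraspanin Tspan8 (-4.78), spermine oxidase Smox (-4.55) and the fast myosin Myh4 (-4.45). Myh4 lost its call in 1 of 20 alternatives. On other probe sets past the test, Myh4 differed by -7.04, Kcnc4 by -3.54, Smox by -2.97 and Tspan8 by -1.73. A further probe set of Tspan8 (-0.71) and the others of Ighm (-2.12 to -0.04) did not pass. Tecrl at 2.72 and Sln at 3.63 in WT TA, and 2310065F04Rik at 3.74 in WT soleus, were at or near background, so their differences are lower bounds.

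In WT, 16 of 18 slow fibre genes were higher in soleus at a median of 4.87 (camera, adjusted p = 8.78e-25), the call that held with an estimated correlation (adjusted p = 0.0447). Of 22 fast fibre genes 12 were lower, Actn3 (-4.02) among them (median -0.73, adjusted p = 4.59e-10, and adjusted p = 0.213 with an estimated correlation). Of 28 glycolysis and glycogen genes 17 were lower and 2 higher, among the former Fbp2 (-2.68) and Phkg1 (-2.27) (median -0.75, adjusted p = 4.52e-06, and adjusted p = 0.213 with an estimated correlation). Of 32 fatty acid uptake and oxidation genes 19 were higher, among them the transporter Cd36 (1.59) and Fabp3 (1.49) (median 0.82, adjusted p = 5.61e-13, and adjusted p = 0.213 with an estimated correlation). On other bright probe sets Cd36 differed by 1.58, past the test, and by 0.80, not past it. Cytosolic heat shock proteins (Hspa1a 3.84; adjusted p = 0.000689, and adjusted p = 0.296 with an estimated correlation) and adipocyte markers (Adipoq 4.61, Cidea at least 3.47; adjusted p = 0.000565, and adjusted p = 0.213 with an estimated correlation) were also higher. The ER chaperone list did not shift between the WT muscles (median 0.09, adjusted p = 0.279).

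Markers of other cells differed between the WT muscles as well. In soleus, endothelial markers (Pecam1 0.97, median 0.14, adjusted p = 0.0152, and adjusted p = 0.274 with an estimated correlation), fibroblast and matrix genes (Fn1 1.84, median 0.29, adjusted p = 0.00525, and adjusted p = 0.715 with an estimated correlation) and tendon markers (Cilp 1.73, median 0.86, adjusted p = 0.00525, and adjusted p = 0.369 with an estimated correlation) were higher. Erythroid markers (Slc4a1 -0.63, median -0.63, adjusted p = 0.0358, and adjusted p = 0.213 with an estimated correlation) and lymphocyte markers (Ighm -4.89, Ms4a1 -0.31, median -0.23, adjusted p = 0.0245, and adjusted p = 0.274 with an estimated correlation) were lower. Immediate early genes had a median of 0.37, with Ier5 (1.42) higher and Nr4a1 (-1.78) lower (adjusted p = 0.0221, and adjusted p = 0.244 with an estimated correlation). The fibroblast call ended without WT soleus replicate 1 (median 0.15) and without WT TA replicate 3 (0.18), and the endothelial median lay between 0.08 and 0.40 with single arrays left out.

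In total 1392 genes differed between the WT muscles, 578 higher and 814 lower in soleus, and 2369 with the replicate block, 1386 of them shared. Camera called 12 lists, 1 with an estimated correlation (0 with the block as well), and fry 11. With the block alone camera called 13, fatty acid and triglyceride synthesis being added. Median centring of the arrays shifted the median of all genes to -0.18 and gave 4096 genes, 17.4% of them higher in soleus; of the 86 genes the naming rule gives for this comparison, 0 turned their direction under it. Fitted on the WT arrays alone 706 genes passed, and leaving out WT soleus replicates 1 and 2 or WT TA replicates 1 and 2 gave 699, 758, 853 and 844.

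Soleus and TA differed in KO mice as well, in 1165 genes, 565 higher and 600 lower in soleus, and in 2194 with the replicate block. The majority turned with the scaling, the table as deposited giving 681 higher and 458 lower, and median centring 513 and 720. Of the 18 slow fibre genes 15 were higher in KO soleus (median 4.24, adjusted p = 2.34e-23, and adjusted p = 0.0537 with an estimated correlation), and 13 of 22 fast fibre genes were lower (median -0.65, adjusted p = 2.04e-10, and adjusted p = 0.228 with an estimated correlation). Of 28 glycolysis and glycogen genes 16 were lower (median -0.88, adjusted p = 4.07e-10, and adjusted p = 0.0948 with an estimated correlation), and 6 of 32 fatty acid uptake and oxidation genes were higher (median 0.18, adjusted p = 0.0041, and adjusted p = 0.832 with an estimated correlation). ER chaperones were lower in KO soleus than in KO TA, 5 of 27 past the test (median -0.33, adjusted p = 0.00677, and adjusted p = 0.788 with an estimated correlation). Stress response targets (median -0.40, adjusted p = 0.0303, and adjusted p = 0.834 with an estimated correlation) and cholesterol synthesis genes (median -0.19, adjusted p = 0.0303, and adjusted p = 0.228 with an estimated correlation) were lower as well. Tendon markers (median 1.30, adjusted p = 6.63e-06, and adjusted p = 0.228 with an estimated correlation) and adipocyte markers (median 1.14, adjusted p = 0.00677, and adjusted p = 0.377 with an estimated correlation) were higher in soleus beside them. So were cytosolic heat shock proteins (median 0.21, adjusted p = 0.00978, and adjusted p = 0.726 with an estimated correlation) and immediate early genes (median 0.25, adjusted p = 0.0101, and adjusted p = 0.228 with an estimated correlation). The stress response call ended without KO soleus replicate 1 (median -0.23) and without KO TA replicate 3 (-0.26), and without KO soleus replicate 3 the adipocyte median was 0.57. Camera called 11 lists, 0 with an estimated correlation, and fry 6 (9 with the block). With the block alone camera called 12, cell cycle genes being added. Fitted on the KO arrays alone 631 genes passed, and leaving out KO soleus replicate 1, KO TA replicate 2 or KO TA replicate 3 gave 585, 610 and 758. Median centring shifted the median of all genes to -0.14.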

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

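Apart from the tests of the difference between the KO effects, the tests in this part were chosen after the results they bear on were seen; the counts over other splits were set beforehand.

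The KO effect differed between soleus and TA, by a test of that difference itself, for 5 genes: 2310065F04Rik (5.55), Mss51 (3.61), Prima1 (3.59), Bhlha15 (-1.50) and Arv1 (-0.61), each given as soleus minus TA on the log2 scale. Alternatives ended the call of Mss51 in 12 of 25, of Prima1 in 13 of 24, of Bhlha15 in 7 of 23 and of Arv1 in 4 of 24 cases, and the soleus values of all but Mss51 lay near the floor, so that the size of these differences cannot be read. It also differed for 9 lists by camera with the preset correlation. Their medians were -0.51 for ER chaperones and folding enzymes, -0.28 for ER-associated degradation, -0.22 for integrated stress response targets, -0.75 for slow fibre genes, -0.11 for glycolysis and glycogen metabolism, -0.06 for the respiratory chain, -0.51 for fatty acid uptake and oxidation, 0.22 for the proteasome and -0.47 for endothelial markers. When the genotype was exchanged within each muscle, 9 of 100 drawn splits gave as many genes as the real 5, and 48 of 100 as many lists as the real 9, so chance cannot be excluded for either count. Each muscle was drawn on its own, so arrays of equal genotype and number, which correlated between the muscles, were not kept together. The highest other values were 635 genes and 17 lists. The split with 635 genes exchanges the genotype in 1 muscle, which turns the difference of the KO effects into their mean, and so points to a structure of the samples, either a KO effect shared by both muscles or variation that arrays of equal genotype and number share.

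Probe sets without a single gene name were outside every gene test. Of 4849 such probe sets kept, 37 differed between KO and WT TA, 19 higher and 18 lower in KO, from 3.04 to -2.74 on the log2 scale.

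In each of the 4 groups, the array numbered 3 lay apart from the others on the first component of variation within groups, which held 48.3% of that variance. A labelling step that reached less far toward the 5 prime ends may account for this: the poly-A spike-ins, added to the RNA, had a 5 prime minus 3 prime log2 value of -2.69 to -2.38 on these 4 arrays and of -1.74 to -1.10 on the other 8, a gap of 0.64. RNA broken down in the tissue would lower actin beyond the fall of the spike-ins, which never were in the tissue. Actin showed a gap of 0.11 in the same direction, but it fell less. Its mean was -0.97 on the 4 arrays and -0.69 on the other 8, against -2.52 and -1.49 for the spike-ins. Gapdh overlapped, at -0.17 to -0.04 and -0.06 to 0.12. These values argue against breakdown as the main source, provided that labelling acts alike on spike-ins and transcripts, which was not tested. No biological explanation was tested.

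Of the 12 genes that fell most in KO TA, 7 are lower in WT soleus than in WT TA and 5, Ampd1, Mettl21e, Casp12, Slc30a2 and Maob, are not past the test for that or are higher. Soleus tissue or a soleus array in place of TA is argued against: the upper quartile of slow fibre genes had moved 2.56% of the way from WT TA to WT soleus, where the 7 had moved by a median of 98.2%, and the 5 lay below both, as Casp12 at 4.44 in KO TA, 7.77 in WT TA and 8.21 in WT soleus. A sequence variant of the strain under the probes, which would lower the signal in both muscles alike, is left open. For the 7 genes above log2 5 in WT soleus the changes differed between muscles by a median of 2.51. The standard error of their mean, taken over these 7 genes and not over arrays, was 0.41. But genes picked for their fall in TA change less in soleus by selection alone, and Mss51 was the 1 of the 7 past the test of the difference. The other 5 stood at a median of 3.31 in WT soleus, where the size of a fall cannot be read. An effect of the genotype also remains a candidate explanation, not tested apart from these.

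For the ER chaperone genes, higher in KO TA by a median of 0.81, more connective tissue cells in the KO samples are argued against: the upper quartile of fibroblast and matrix genes was 0.32, below the lower quartile of 0.47 of the ER chaperones, and 0 of 20 such genes reached the ER median. The arrays numbered 3 as the source are argued against too, since without them the median was 0.75 with 27 of 27 genes positive. A response of the muscle to the loss of H6pd may explain the pattern, as a hypothesis found and tested on the same data, and the H6pd signal did not check the genotype labels.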

How the results depend on the processing

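The alternatives without the arrays numbered 3, with a mean log2 above 5, and with the block for list tests with fry or an estimated correlation were chosen after the data were seen. Over 127 results on named genes, 2362 alternative values kept direction and side of the threshold, 297 kept the direction but no longer passed, 41 came to pass and 10 reversed. The values kept include those of genes that did not pass in the main setting and stayed so. All losses of a call fall on the genes that passed there, so these counts overstate how stable the calls are. No list called in the main setting was called in the opposite direction under any alternative of camera with the preset correlation. Where no cause is named below, the cause was not tested.

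The 4 genes of KO soleus became 1 with no filter, 7 with median centring, 2 with no trend, 1 with the robust fit, 360 with array weights and 0 with only the arrays compared (limma; 1140 unadjusted in the main setting). Leaving out single arrays gave 3 to 30. With the block 4 passed, 3 of them shared, although equal numbers did not pair these arrays by the limit of 0.1 (correlations of 0.43, 0.09 and 0.61). The 368 genes of KO TA became 4 with only the arrays compared, 913 with the replicate block and 56 with the arrays numbered 3 left out. Single arrays left out gave 85 to 398. The 5 genes whose KO effect differed became 3 with no filter, 1 with no trend, 10 with array weights, 15 with the block by animal, 8 without the arrays numbered 3 and 1 with a mean log2 above 5, and 1 to 20 with single arrays left out. With the replicate block 4 passed, 3 of them shared, and Mss51 and Prima1 did not.

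Between the WT muscles 1392 genes became 4096 with median centring, 2800 with array weights, 706 with only the arrays compared, 2369 with the replicate block and 2670 by animal, and 699 to 1281 with single arrays left out. Between the KO muscles 1165 became 631 with only the arrays compared, 2194 with the replicate block and 2287 by animal, and 585 to 1072 with single arrays left out. Genes changed in both muscles went from 0 to 1 with the stricter filter, 94 with array weights, 2 with the replicate block, 1 by animal and 1 with a mean log2 above 5, and 0 to 11 with single arrays left out. Fits on only the arrays compared have fewer arrays to estimate the spread from.

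Of the 12 lists in KO soleus, 0 were called with an estimated correlation, 2 by fry, and with the block 0 with an estimated correlation and 0 by fry. Beside the 13 in KO TA, 0 lists were called with an estimated correlation, and 0 with the block as well. Fry called 6 there, among them the erythroid list, which is not 1 of the 13. Of the 9 that differed between muscles, 0 were called with an estimated correlation and 0 by fry, and with the block 0 and 1. Camera with the preset correlation called 10 with the block. Of the 12 between WT muscles 1 was called with an estimated correlation and 0 with the block as well. Of the 11 between KO muscles 0 were called with an estimated correlation, 6 by fry, 7 with a mean log2 above 5 and 0 with the block and an estimated correlation. An estimated correlation counts genes of a list that vary together as fewer independent ones.

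These values reversed: Arrdc2 in KO soleus to 0.18 without WT soleus replicate 3 (single arrays left out: -2.29 to 0.18). In KO TA, Sln went to -0.11 without KO TA replicate 3 (-0.11 to 2.16). Postn went to -0.09 without the arrays numbered 3 and to -0.13 without WT TA replicate 3 (-0.13 to 1.12). H6pd went to -0.16, -0.13 and -0.19 without KO TA replicate 3, WT TA replicate 1 and WT TA replicate 2 (-0.19 to 0.64). On other probe sets Ighm in KO TA gave 0.04, Ern1 in the difference of effects 0.36 and Tpm3 between the WT muscles -0.08. That Ighm probe set had a mean log2 of 2.92, near the floor. The filter level of log2 2.76 lay in the floor of the table, so genes near it, such as Bhlha15 and Arv1, rest on small differences over background.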

Other observations

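The mean of the KO effects in both muscles and the test of genes beside H6pd were chosen after the data were seen, and the counts over other splits were set before.

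For the mean of both KO effects 635 genes passed limma, 314 higher and 321 lower, of which 299 were among the TA calls and 332 were called in neither muscle; 626 had the same sign in both. This fit takes the 12 arrays as independent, while arrays of equal genotype and number correlated at 0.33. With these as a random block 193 genes passed, all among the 635, and with both arrays averaged for each of the 6 such pairs 1 passed (1594 at an unadjusted p under 0.05), so the 635 is no safe count if they come from the same mouse; with the replicate number as a fixed block it was 1311. The values that follow are from the fit without a block. Nmrk2 (2.87), Mthfd2 (2.65), a mitochondrial folate enzyme, Ankrd1 (2.57), Myh3 (1.96), Manf (1.89), Ddit3 (1.61) and Dnajb9 (1.57) were among the higher genes. Ampd1 (-3.26), Mettl21e (-3.18), Slc30a2 (-2.53), Cish (-2.25), Frzb (-2.15) and Casp12 (-2.07) were among the lower. Of 27 ER chaperones and folding enzymes 12 rose, at a median of 0.58 (adjusted p = 1.08e-16, and adjusted p = 0.114 with an estimated correlation). Of 56 genes of the respiratory chain and tricarboxylic acid cycle 8 fell, at a median of -0.17 (adjusted p = 7.51e-10, and adjusted p = 0.375 with an estimated correlation). The covariance of the KO effects of both muscles across genes was 0.0612, against 0.00966 from the deviations of replicates.

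Genes beside a targeted locus can keep the DNA of the strain in which it was targeted. Up to 100 tested genes were taken on each side of H6pd on its chromosome, which gave 172 genes. Of these, 4 (2.33%) had p under 0.01 with the same sign in both muscles, against 169 of 12836 other genes (1.32%, Fisher's exact test, 2-sided p = 0.295, odds ratio 1.78, 95% interval 0.475 to 4.74). The 4 were Cptp (-0.48 in soleus, -0.65 in TA), Mrpl20 (-0.44, -0.58), Park7 (-0.47, -0.80) and Ssu72 (0.53, 0.89). The interval leaves a kept region of the targeted strain open.

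With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. KO against WT soleus gave 4 genes, with 9 as the highest of the other splits, and 3 of 10 splits gave as many; for lists it was 12, 18 and 3 of 10. KO against WT TA gave 368 genes against a highest other value of 1 (1 of 10), and 13 lists against 12 (1 of 10); among the 4 splits that part as many replicate pairs, the highest other values were 0 genes and 9 lists. The WT muscles gave 1392 genes against 2 (1 of 10) and 12 lists against 12 (2 of 10), and the KO muscles 1165 genes against 3 (1 of 10) and 11 lists against 12 (4 of 10). Over all splits, regrouped arrays thus called more lists than the real groups in soleus and between the KO muscles, as many between the WT muscles and nearly as many in TA. The highest values in soleus and between the KO muscles came from splits that kept arrays of equal number together. Among splits that part as many replicate pairs as the real one, the highest other values in soleus were 1 gene and 11 lists. They were 0 genes and 12 lists between the WT muscles, and 0 genes and 9 lists between the KO muscles. Such splits are too few for a share under 0.05 as well. For genes changed in both muscles the real count was 0, which each of the 100 drawn splits reaches by construction (100 of 100, highest other 0), so these splits say nothing about chance.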
